A study of Homo sapiens with 8 samples.

How the data were processed

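RNA from K562 cells was measured on 8 Affymetrix Human Exon 1.0 ST arrays, 4 of control cells and 4 of cells treated with 0.5 mM amiloride for 24 h. Per the labels, total RNA was isolated with a column kit, checked on a Bioanalyzer and labelled with biotin. The values were normalized by the authors with Partek software, as the series text and the submitters' processing notes state. The background correction, the normalization method, the summarization method and the software version are not given in the sources used here. The deposited values of single probe sets are on a log2 scale, with nearly the same mean in every array. The base of the log2 scale was checked against the authors' ratios: for 9533 genes with equal probe set numbers in both files, the difference of the group means over probe sets lay within 0.01 of log2 of the deposited ratio in 99.4% with all 4 controls, and in at most 17.8% with any 3 of them. The deposited ratio is control over amiloride per transcript cluster, per the file headers. The deposited p-value belongs to that contrast in the authors' analysis of variance, whose terms are the treatment, the probe set, the sample and the interaction of treatment and probe set, per the file headers. A second p-value of the interaction and the number of probe sets are given per the file headers too. The signed fold change in the deposited file is a score made from the same ratio and was not used separately. All 8 columns of values were matched to a sample by name, and 0 were left out. At most 0.028% of probe sets had identical values in any pair of arrays, so each array was counted as its own sample.

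Probe sets were named through the platform annotation given with the data. Of 232448 probe sets, 216780 had 1 gene symbol, 2335 had several and 13333 had none there, and only those with 1 symbol were used for genes. The annotation is old: of 16573 symbols, 14260 are current symbols and 2309 synonyms in NCBI RefSeq (GCF_000001405.40, GRCh38.p14), and 4 were not matched. Symbols are printed as the annotation gives them. The authors' genome build is not given in the sources used here, so no coordinates are printed. Cytogenetic bands are those of the authors' deposited table. RefSeq was used only for names and for which genes neighbour each other.

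A gene's value was the median log2 value over its probe sets, for 15417 genes with at least 3. Genes with a mean over the 8 arrays under the 25th percentile (3.78) were left out, which left 11563. Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. SE is the moderated standard error of limma. Probe set usage was tested with diffSplice in limma, which sets the log2 difference of each probe set against the other probe sets of its gene. It ran on 144592 probe sets at or above the 25th percentile (3.61) in 10790 tested genes with at least 4 such probe sets. A probe set was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1 from the rest of the gene, and genes were called on the Simes-adjusted p. For 31 gene lists fixed before the data were examined, with at least 5 tested members each, camera was run with its preset correlation of 0.01, again with an estimated correlation, and fry beside it. The 2 lists for probe set usage were compared with the other tested genes by Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

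The genes and probe sets named follow a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05 and groups that do not overlap. In each list called by camera it takes up to 4 members with the smallest p and the member with the largest p. It adds BCL2L1, HIPK3, BCR, ABL1, MYC, SRSF1, AKT1, MAPK3, PPP1CA and SCNN1A whatever their values. For probe sets it takes the 10 with the largest difference from the rest of their gene, at most 1 per gene, then for up to 15 genes of the usage lists the called probe set with the smallest p, and the probe set with the smallest p in BCL2L1, HIPK3, BCR and ABL1. Other genes of the rule were not analysed here.

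Each test was also tested on simulated data drawn from the means and residual SDs of these arrays. With 200 changed genes among 11563, the gene test recovered 10.0% of those changed by 0.5 on the log2 scale, 72.0% at 1, and all at 2 and 3, with 7 false calls among 148. The real comparison called 5865 genes, and the Benjamini-Hochberg limit is less strict with that many calls. The gene test was not simulated at that scale, so its recovery there was not measured. The diffSplice test on 144592 probe sets did not hold its error rate: with 200 changed probe sets 71.7% of its 575 calls were of unchanged ones, and with 9000 changed 17.0% of 9488. Of the genes called by its Simes-adjusted p in these simulations, 76.1% and 8.77% held no changed probe set. The test pools the spread over a gene's probe sets, while the simulated probe sets each kept their own. A splicing index, each probe set minus its gene's median in each array, gave 4.23% and 9.38% calls of unchanged probe sets in the same simulations. It recovered 33.1% of changes of 1 and 92.9% of changes of 2 on the log2 scale with 9000 changed probe sets, where diffSplice recovered 50.8% and 99.2%. Camera called both lists shifted by 0.5 and 0 of the other lists, on simulated genes that were independent of each other.

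Alternatives fixed before the data were examined were the replicate number as a block, each array left out in turn, arrays centred on their median, quantile normalization, means in place of medians over probe sets, medians over brighter probe sets only, no signal filter or a filter at the 50th percentile, a trended robust prior or no moderation, usage only in genes changed by under 0.5 on the log2 scale, the splicing index, and both other list tests. A pseudocount was not needed, since the values are logs. Centring each array on the median of the tested genes, or on the median difference of the tested genes, was added after the data were seen. All 35 splits of the 8 arrays into 4 and 4 were run. Probe sets with several symbols were left out.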

Results

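Total RNA from K562 cells, a human cell line established from chronic myeloid leukemia that carries the BCR-ABL1 fusion, was measured on Affymetrix Human Exon 1.0 ST arrays. These arrays carry several probe sets along the exons of each gene, so that the level of a gene and the relative use of its parts can both be read. The 8 arrays fall into 2 groups, 4 of untreated control cells and 4 of cells treated with 0.5 mM amiloride for 24 h. Amiloride is a potassium-sparing diuretic that blocks epithelial sodium channels. The title of the series states the question as whether amiloride alters splicing in leukemic cells. The series text names 3 control samples where 4 are listed, and all 4 were used. Each array gave values for 232448 probe sets, with a median log2 signal between 5.70 and 5.73. The spread of signal differed between the groups. The 25th percentile was 3.58 to 3.68 in control arrays and 3.46 to 3.53 in amiloride arrays. The 75th percentile was 8.14 to 8.23 and 8.27 to 8.34. This difference follows the groups, so its source cannot be told apart from the treatment. Pearson correlations across probe sets, which are not independent replicates, were 0.969 to 0.986 within the control group, 0.984 to 0.990 within the amiloride group and 0.922 to 0.961 between the groups. Control replicate 1 had the lowest mean correlation with its own group, 0.973. The series text does not say whether each array came from a separate culture, so the p-values measure the spread between these arrays, which may be technical, and the number of arrays limits their precision.

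The genes that amiloride raised most were dim in control cells, and all of the 10 largest rises began under a log2 value of 5.63. The largest rise of a median over probe sets was that of C1orf162, at 1p13.2 in the authors' deposited table, from a log2 value of 4.69 ± 0.39 (SD, n = 4) to 11.08 ± 0.28 (SD, n = 4), a difference of 6.39 ± 0.21 (SE) or 84.1-fold. SGK1, a serum- and glucocorticoid-regulated kinase that acts on sodium channels, rose by 5.16 ± 0.23 on the log2 scale, which is 35.7-fold. PDZK1IP1 rose 24.3-fold, and PDCL2 and RRH rose by 4.74 and 4.59 on the log2 scale. The other genes among the 10 largest rises were VDAC2, a channel of the outer mitochondrial membrane read by only 3 probe sets, the monocarboxylate transporter family member SLC16A4, TMEM171, OVGP1 and the amine oxidase AOC3, with log2 differences from 4.13 to 4.43. The control values of PDCL2, RRH, SLC16A4, TMEM171 and AOC3 lay under the signal limit of 3.78, so the sizes of these rises and their order are not exact. The largest fall was that of TLCD1 at 17q11.2, from 7.96 ± 0.46 (SD, n = 4) to 5.02 ± 0.33 (SD, n = 4), a log2 difference of -2.93 ± 0.23 (SE) or 7.64-fold. TMEM177, FAM83D and TUBB1, the platelet beta-tubulin, fell 6.86-fold, 6.78-fold and 6.36-fold. FIGNL1, MTERFD3, C22orf29, MAT2A, the enzyme that makes S-adenosylmethionine, the thrombin receptor F2RL3 and ZNF485 fell 5.13-fold to 5.71-fold. In each of these 20 genes the 4 amiloride values lay outside the range of the 4 control values, and the limma adjusted p was 1e-04 or smaller. Gene values here are medians over probe sets, and they hide unequal probe sets in some of these genes. In the authors' deposited table, whose ratios equal those of mean values, the amiloride over control ratio was largest for SGK1 among these genes, at 29.9, and was 23.8 for C1orf162. That table gave 12.6 for PDCL2, 9.75 for PDZK1IP1, 6.45 for VDAC2 and 3.92 for TMEM171, where the medians gave 26.6-fold, 24.3-fold, 21.6-fold and 18.8-fold. For the 10 falls its control over amiloride ratio ran from 2.22 for C22orf29 to 7.88 for TLCD1.

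**Figure D1:**
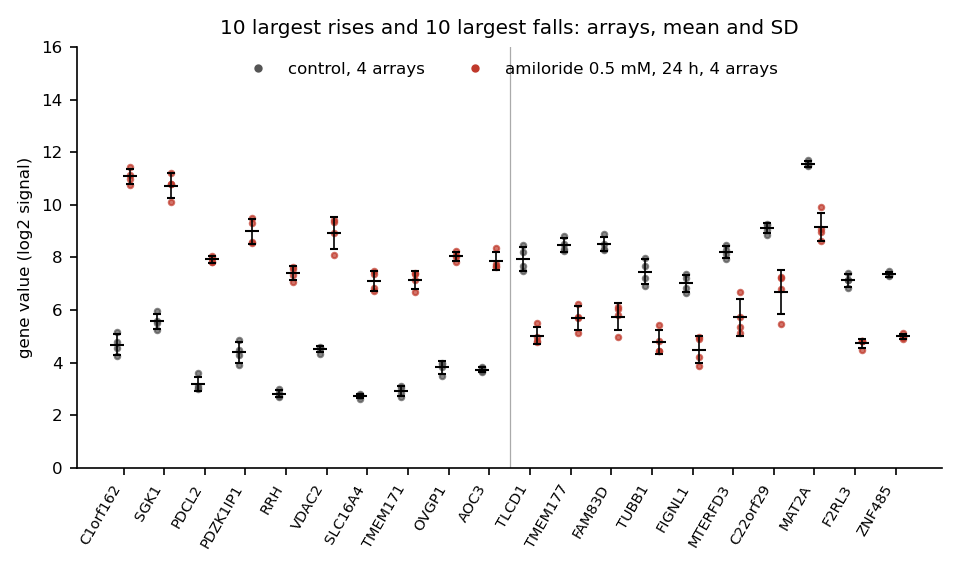
Log2 gene values of each array (points) with the mean and SD (black) for the 10 genes with the largest rise and the 10 with the largest fall, control arrays in grey and arrays of cells treated with amiloride in red. The 2 groups do not overlap in any of the 20 genes, and C1orf162 went from 4.69 to 11.08.

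Over all 11563 genes tested, 5865 (50.7%) changed at an adjusted p under 0.05, 2770 of them higher and 3095 lower after amiloride. A change of at least 2-fold was found for 1805 genes, 1344 higher and 461 lower, or 2.92 rises per fall. At 4-fold there were 296 rises and 35 falls, and 54 genes rose at least 8-fold while the largest fall was 7.64-fold. With means in place of medians over probe sets the 4-fold counts were 161 rises and 10 falls, and 26 genes rose at least 8-fold. The 2 groups did not overlap in 5306 genes (45.9%), where chance gives 2.86%. The median log2 difference of the tested genes was -0.14. The balance of rises and falls depends on where zero is set. With each array centred on the median of its tested genes, the median difference moved by -0.19, to -0.33. After that centring 2177 genes were higher and 4875 lower. There were then 1031 rises and 886 falls of at least 2-fold, and 213 rises and 45 falls of at least 4-fold. With each array centred instead on the median difference of the tested genes, 3040 were higher and 2353 lower, with 1515 rises and 352 falls of at least 2-fold and 340 and 26 of at least 4-fold. Both centrings were chosen after the data were seen.

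**Figure D2:**
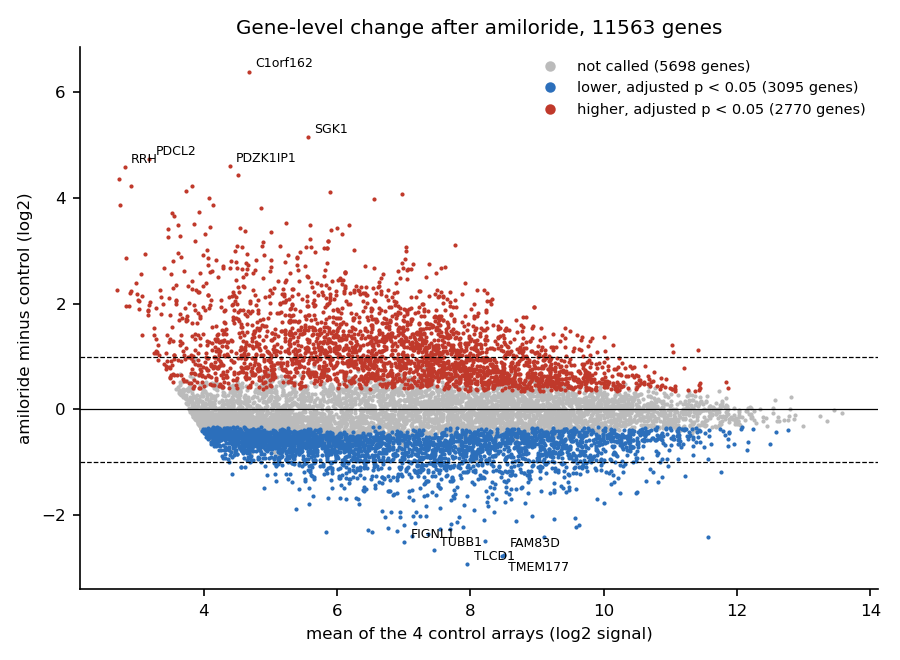
Log2 difference between the amiloride and control means of 11563 genes against the mean log2 signal of the 4 control arrays, with genes called higher in red, lower in blue and not called in grey. Dashed lines mark a 2-fold change, and 296 genes rose while 35 fell at least 4-fold.

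Several groups of splicing genes had more members that rose than fell after amiloride, although none of the list calls held with an estimated correlation (adjusted p = 0.706 for the core spliceosome and 0.615 for both the SR proteins and the kinases and phosphatases). Of 48 tested components of the core spliceosome, 16 rose, 2 fell and 30 did not pass the test. SLU7, which acts in 3' splice site choice, rose 4.36-fold (log2 difference 2.13 ± 0.17, SE), U2AF1, the small subunit of the factor that binds the 3' splice site, rose 3.86-fold as the median of 4 probe sets but 1.99-fold in the authors' deposited table, and the helicase DHX8 and PRPF3 rose 2.71-fold and 2.14-fold. SNRPD1 differed by -0.01 ± 0.14. Of 20 tested SR proteins and relatives, a family of serine- and arginine-rich splicing factors, 9 rose and 0 fell. SFRS6 (current symbol SRSF6), TRA2A, SFRS11 (SRSF11) and SFRS12 (SREK1) rose 2.72-fold, 2.83-fold, 2.57-fold and 2.83-fold, while SFRS2 (SRSF2) differed by 0.00 ± 0.16 on the log2 scale as a median but was called lower with means over its probe sets (-0.42, adjusted p = 0.0036). In the authors' deposited table the TRA2A cluster of 9 probe sets rose 2.86-fold, while its other cluster, of 3, had a ratio of 1.03. Of 27 tested genes of the list of splicing kinases and phosphatases 13 rose and 3 fell. Whether each member, HIPK3 among them, acts on splicing factors was not checked here. HIPK3 rose 11.3-fold, CLK1 and CLK4, kinases of SR proteins, rose 7.55-fold (4.94-fold in the authors' deposited table) and 7.05-fold, and the phosphatase subunit PPP1R10 rose 2.99-fold, while PPP1CA differed by 0.02 ± 0.13. The camera adjusted p was 0.0188 for the core spliceosome, 0.0364 for the SR proteins and 0.0188 for the kinases and phosphatases. Adjusted over the list alone, 14 spliceosome genes rose and 2 fell, 9 SR genes rose and 0 fell, and 13 kinase and phosphatase genes rose and 3 fell. The SR call was also lost without control replicate 1 (adjusted p = 0.0676) and without amiloride replicate 3 (adjusted p = 0.0569), with quantile normalization (0.0557) and with centring on the median of tested genes (0.0629). After that centring the list medians of the 3 groups were 0.02, 0.06 and 0.01. Then 13 spliceosome genes rose and 5 fell, 6 SR genes rose and 3 fell, and 10 kinase and phosphatase genes rose and 4 fell. With centring on the median difference these counts were 19 and 2, 9 and 0, and 13 and 3. With genes under the 50th percentile left out all 3 calls were lost, at adjusted p values of 0.0971, 0.146 and 0.139. The list of hnRNPs was not called as a group, with 5 of 26 higher, 4 lower and an adjusted p of 0.547.

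Genes of the immediate early response, of the integrated stress response and of mitosis were called higher as lists by camera. None of these calls held with an estimated correlation (adjusted p = 0.615, 0.706 and 0.706). Of 28 tested immediate early genes 14 rose and 4 fell. NR4A2 rose 9.31-fold, KLF10 8.71-fold, KLF6 5.93-fold and the MAP kinase phosphatase DUSP1 3.81-fold, while BTG2 differed by -0.14 ± 0.25 on the log2 scale. Of 40 tested genes of the ATF4 pathway, which responds to amino acid and unfolded protein stress, 15 rose and 3 fell. With centring on the median of tested genes 11 rose and 8 fell, and the list median went from 0.27 to 0.09. With centring on the median difference 19 rose and 3 fell. The cystine transporter SLC7A11 rose 5.62-fold, and PPP1R15A, which recruits a phosphatase to eIF2 alpha, 3.84-fold. ATF5 and ATF3 rose 3.73-fold and 2.34-fold (2.03-fold and 1.67-fold in the authors' deposited table), and GARS differed by 0.01 ± 0.15. Of 37 tested genes of G2 and mitosis 15 rose and 2 fell. UBE2C, HMMR and TTK rose 3.76-fold, 2.92-fold and 2.55-fold, CDC25B fell 2.04-fold, and KIF2C differed by 0.00 ± 0.19. The camera adjusted p was 0.0188 for the immediate early list, 0.0289 for the ATF4 list and 0.0188 for the mitotic list. The ATF4 call was lost without control replicate 1 (adjusted p = 0.0676) and without amiloride replicate 1 (adjusted p = 0.0839). With genes under the 50th percentile left out the immediate early, ATF4 and mitotic calls were all lost, at adjusted p values of 0.0660, 0.157 and 0.0971. Adjusted over the list alone, 14 genes rose and 4 fell in the immediate early list, 14 rose and 3 fell in the ATF4 list, and 15 rose and 2 fell in the mitotic list.

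Lists of ribosome biogenesis, sterol synthesis and blood lineage genes were called lower by camera, but none of these calls held with an estimated correlation (adjusted p = 0.706 for each). Of 34 tested genes of ribosome biogenesis, a set that includes MYC, 15 fell and 2 rose. RRP9 fell 2.09-fold, MYBBP1A 1.97-fold, GNL3 1.85-fold and BOP1 1.71-fold, while NOC3L differed by -0.09 ± 0.31. Of 26 tested genes of cholesterol and fatty acid synthesis and their regulators 10 fell and 0 rose. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, fell 2.99-fold, the transcription factor SREBF1 2.02-fold, and the enzymes DHCR7 and LSS 1.83-fold and 1.74-fold, while ACSS2 differed by 0.00 ± 0.22. Of 15 tested megakaryocyte genes 5 fell and 0 rose. TUBB1 fell 6.36-fold and F2RL3 5.25-fold (4.67-fold and 3.38-fold in the authors' deposited table). The transcription factor NFE2 fell 2.57-fold and PECAM1 by 1.14 ± 0.23 on the log2 scale, while ITGA2B differed by -0.08 ± 0.17. Of 35 tested erythroid, globin and heme genes 12 fell and 0 rose. The erythropoietin receptor EPOR fell 3.84-fold, GFI1B 1.95-fold and ZFPM1 1.76-fold, and BLVRB differed by 0.00 ± 0.15. Markers of lymphoid cells, which K562 cells are not, also moved, with 8 of 15 lower and 0 higher. With quantile normalization 4 were lower and 0 higher. CD7, NKG7 and CD5 fell 1.71-fold, 1.71-fold and 1.54-fold, CD79B fell by 0.68 ± 0.16 on the log2 scale, and CD3D differed by 0.12 ± 0.32. CD79B and CD5 began at 4.92 and 4.66, under the median control signal of genes, 5.63. CD7, NKG7 and CD3D began above it. All genes under it had a median log2 difference of -0.19, so the falls of CD79B and CD5 are not fully set apart from that of dim genes. Markers of myeloid and of stromal or epithelial cells were not called, with adjusted p values of 0.330 and 0.590.

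The camera adjusted p of the lists that were lower was 0.0188 for ribosome biogenesis, 0.0188 for cholesterol, 0.0364 for megakaryocyte, 0.0455 for erythroid and 0.0498 for lymphoid genes. The megakaryocyte call was lost without control replicate 1 (adjusted p = 0.0685), with quantile normalization (0.0603) and with no signal filter (0.149), and that of ribosome biogenesis without amiloride replicate 1 (adjusted p = 0.0502). The erythroid call was lost in 4 of the 8 runs that left out 1 array, with an adjusted p of up to 0.0876, with no signal filter (0.107) and with centring on the median difference (0.0524). The lymphoid call was lost in 6 of 8 such runs, with an adjusted p of up to 0.112, with the replicate block (0.0579), with quantile normalization (0.169), with means over probe sets (0.0861), with brighter probe sets only (0.107) and with centring on the median of tested genes (0.0660). Adjusted over the list alone, 14 genes of ribosome biogenesis, 8 of cholesterol synthesis, 5 of the megakaryocyte list, 12 of the erythroid list and 9 of the lymphoid list fell. In all, 11 of 31 lists fixed before the data were examined were called, 6 higher and 5 lower. Camera with an estimated correlation called 0 lists, with 2 at an unadjusted p under 0.05, the immediate early genes and the splicing kinases. The directional test of fry, which does not compare a list with other genes, called 21.

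**Figure D3:**
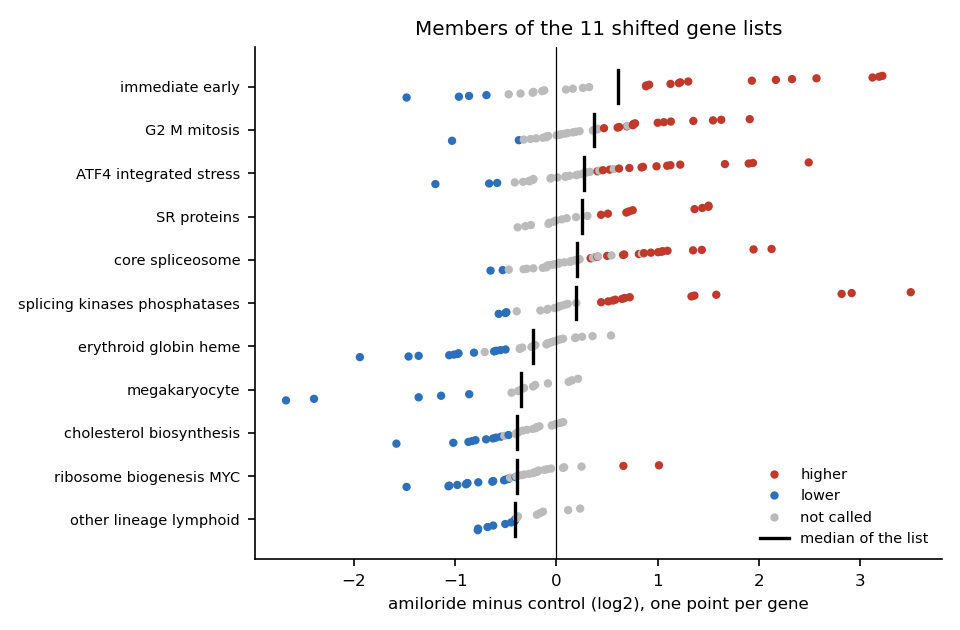
Log2 difference between amiloride and control for each member of the 11 lists called by camera, coloured by the gene's own call, with the list median as a black bar. Medians run from -0.41 for lymphoid markers to 0.60 for immediate early genes; under each of 4 other scalings every one of these medians kept its sign, the smallest being 0.01.

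Genes chosen in advance for their part in BCR-ABL1 signalling or in known responses to amiloride differed among themselves. HIPK3, at 11p13, rose from 6.18 ± 0.41 (SD, n = 4) to 9.67 ± 0.18 (SD, n = 4). MYC, read by 3 probe sets, fell 2.79-fold (log2 difference -1.48 ± 0.30, SE, adjusted p = 0.0018), and the kinase AKT1 fell 1.48-fold (-0.57 ± 0.13, adjusted p = 0.0047). The authors' deposited table gave MYC, over 5 probe sets, a control over amiloride ratio of 1.99. BCR differed by -0.07 ± 0.14, ABL1 by 0.26 ± 0.15, the apoptosis regulator BCL2L1 by 0.04 ± 0.15, the splicing factor SFRS1 (current symbol SRSF1) by -0.03 ± 0.13 and the kinase MAPK3 by -0.39 ± 0.16. None of these 5 was called, with adjusted p values of 0.693, 0.153, 0.817, 0.874 and 0.0611. For BCL2L1 the authors' deposited table gave an amiloride over control ratio of 0.890, so its direction is not settled. Under alternatives MAPK3 was called lower in 5 settings, such as quantile normalization (adjusted p = 0.0315), and ABL1 higher with means over probe sets (adjusted p = 0.0264). SCNN1A, the alpha subunit of the epithelial sodium channel, lay under the signal limit at 3.46 ± 0.18 in control and 3.27 ± 0.15 in amiloride arrays (SD, n = 4) and was not tested. Of 13 tested transporters and channels of the kind that amiloride acts on, 3 were higher and 5 lower, and the list was not called (adjusted p = 0.774).

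Probe sets of many genes moved apart from the other probe sets of their gene. In LEPR, the leptin receptor, probe set 2340509 rose from 3.05 ± 0.16 (SD, n = 4) to 9.31 ± 0.49 (SD, n = 4), a log2 difference of 5.62 from the other probe sets, while the gene's median differed by 0.29 on the log2 scale. Probe set 2670937 of CCDC13 and probe set 3072041 of TNPO3 rose by 5.09 and 4.55 more on the log2 scale than the rest of their genes, and probe set 2774837 of PAQR3 by 4.85 more. All 4 lay under the probe set signal limit of 3.61 in control arrays, so the sizes and their order are not exact. In TNPO3 1 of 25 tested probe sets was called, but in CCDC13 17 of 18 were, so that CCDC13 had no uniform rest of the gene. The opposite held for probe set 2770037 of PDCL2, which moved by -0.58 on the log2 scale while the gene rose by 4.74, and for single probe sets of TMEM171, C1orf162, ACRC, C2orf42 and SNX16, which lay below the rest of their genes by log2 differences of -4.40 to -4.92. The C1orf162 probe set differed by 0.57 by itself, and the other 4 went down while their genes rose. The SNX16 probe set ended under the signal limit, so its size is not exact. Most tested probe sets were called in C1orf162 (6 of 6), ACRC (6 of 7), PDCL2 (4 of 5) and TMEM171 (3 of 4), so these genes had no uniform rest either. In all, 8959 of 144592 probe sets (6.20%) were called by diffSplice at an adjusted p under 0.05 and at least 2-fold, 4122 higher and 4837 lower than the rest of their gene, in 4150 genes. By the Simes-adjusted p, 5728 of 10790 genes (53.1%) had differential probe set usage, and 2478 of these were not called as changed at gene level. On simulated arrays diffSplice called too many: with 9000 changed probe sets, 1613 of its 9488 calls were of unchanged probe sets, and with 200 changed probe sets 412 of 575 were. A splicing index tested with its own spread for each probe set called 7256, of which 5689 were called by both in the same direction, in 3098 genes.

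Among genes that regulate splicing, 39 of 45 tested (86.7%) had differential probe set usage, against 53.1% of all genes (two-sided Fisher's exact test, odds ratio 5.78, p = 2.96e-06, adjusted p = 5.93e-06). Adjusted over the list alone the count was 40. This comparison rests on the Simes calls of diffSplice, which called too many on simulated arrays, and it was not repeated with the splicing index. It was not matched for gene-level change, signal or number of probe sets. In genes changed at least 2-fold 15.9% of probe sets were called, against 4.35% in other genes, so an excess particular to splicing regulators is not settled. Of the genes listed in advance as known for alternative splicing, 29 of 48 (60.4%) had it, which did not differ from the other genes (two-sided Fisher's exact test, p = 0.385), and 29 did when adjusted over the list alone. In KHDRBS1, the RNA-binding protein Sam68, probe set 2328490 rose from 3.06 ± 0.15 (SD, n = 4) to 7.32 ± 0.25 (SD, n = 4), while the gene's median differed by -0.22. Probe sets of RBM39, LUC7L, HNRNPM, MBNL2, the survivin gene BIRC5, CASP2, HNRNPH3 and HNRNPC rose 9.67-fold, 9.08-fold, 6.72-fold, 6.50-fold, 5.45-fold, 4.88-fold, 4.41-fold and 3.61-fold more than the rest of their genes. The control values of KHDRBS1, HNRNPM and HNRNPH3 were also under the probe set signal limit. In LUC7L 9 of 16 tested probe sets were called, so that LUC7L had no uniform rest of the gene. Probe sets of CLK4, RBM25, SF1, HNRPDL, SFRS2 and SFRS10 (current symbol TRA2B) were lower than the rest of their genes by 11.8-fold, 7.81-fold, 7.38-fold, 3.86-fold, 3.13-fold and 2.70-fold. The splicing index did not call the SF1 probe set. In BCR, probe set 3939186 was lower than the rest of the gene by 1.03 ± 0.22 (log2, SE; adjusted p = 0.000279). In HIPK3, 3 of 20 tested probe sets were called. Probe set 3325945, with the smallest p, was 3.33-fold higher than the rest, with a control SD of 1.56 on the log2 scale. The splicing index did not call probe set 3325945. The other called probe sets of HIPK3 differed from the rest by -1.66 ± 0.31 and 1.04 ± 0.31 (log2, SE). Probe set 3902524 of BCL2L1 was lower by 0.65 ± 0.14 than the rest of the gene (adjusted p = 0.000502), under the 2-fold limit, and no probe set of ABL1 was called, the smallest adjusted p being 0.505.

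**Figure D4:**
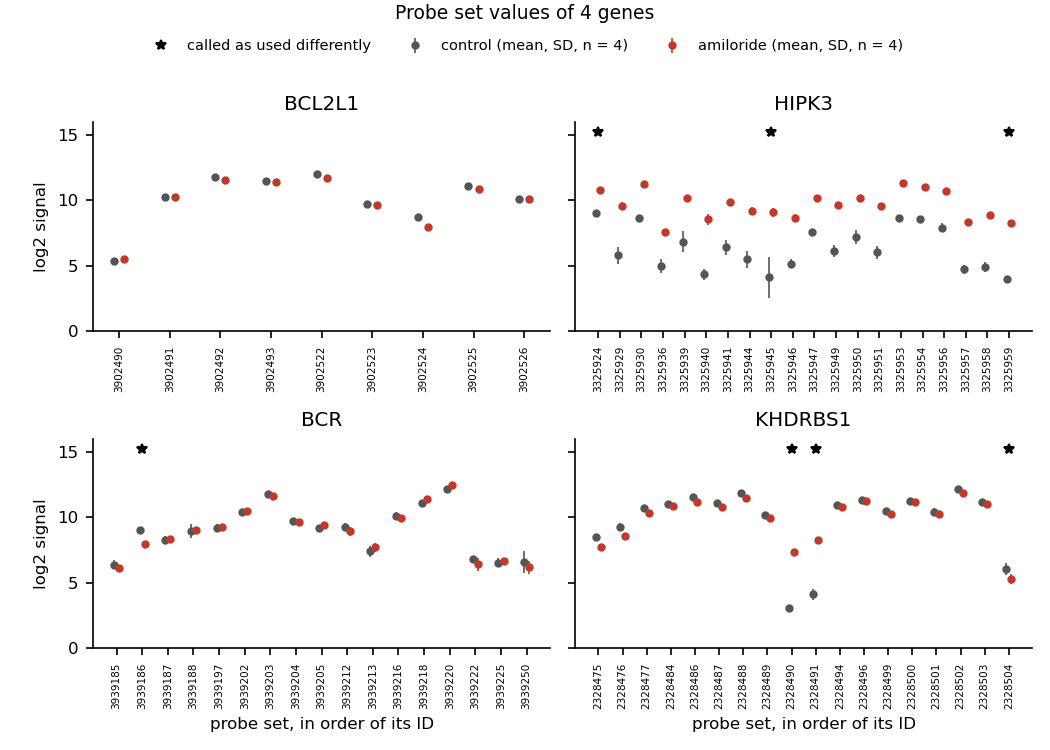
Log2 signal of each tested probe set of BCL2L1, HIPK3, BCR and KHDRBS1 in order of probe set ID, with the mean and SD of 4 control arrays in grey and of 4 arrays of cells treated with amiloride in red, and stars over probe sets called as used differently. HIPK3 was higher over its whole length, whereas probe set 2328490 of KHDRBS1 went from 3.06 to 7.32 while the gene's median differed by -0.22.

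The authors' deposited table gives 17753 transcript clusters with their own ratio and p. Of these, 5789 were higher and 11964 lower in amiloride in the authors' deposited table, and 11073 had a p under 0.05. A p for the interaction of treatment and probe set was given for 16981 clusters in the authors' deposited table, and 10588 of them were under 0.05. For 10977 genes in both sources, 93.0% had the same direction in the authors' deposited table and in limma, and the correlation of the log2 differences across genes, which are not independent replicates, was 0.957. Of 4837 genes with an adjusted p under 0.05 both in limma and when the p-values of the authors' deposited table were adjusted here by Benjamini-Hochberg, 4833 had the same direction.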

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

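The centring on tested genes, the rises and falls by control signal, the comparison without control replicate 1 among rises and falls, the median of all dim genes, the comparison with bright genes and the count over balanced splits were tests chosen after the result was seen. The other tests here were written before.

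Within the groups, 234 sets of 4 arrays were searched for a single array far from the others by Dixon's ratio, and 7 (2.99%) passed it, where chance gives about 1 in 20. They were F2RL3 (ratio 0.912, amiloride replicate 3 at 4.47 against 4.81 to 4.84), RRP9 (0.872, amiloride replicate 4 at 8.88 against 8.52 to 8.56), MAPK3 (0.843, amiloride replicate 1 at 9.45 against 8.83 to 8.93), UBE2C (0.848, control replicate 4 at 4.73 against 5.51 to 5.64) and LSS (0.882, control replicate 2 at 9.02 against 9.26 to 9.29). Probe set 3142564 of SNX16 (0.889, amiloride replicate 4 at 3.20 against 3.45 to 3.48) and probe set 3674980 of LUC7L (0.883, amiloride replicate 2 at 7.50 against 7.28 to 7.30) were the others. Without amiloride replicate 1, MAPK3 was called as lower, with an adjusted p of 0.0115. Probe sets with no gene symbol here carried signal that the comparisons did not use: 861 of 8575 tested rose and 612 fell at least 2-fold, where 11.9% of the named probe sets rose and 5.88% fell.

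Whether any grouping of the arrays gives such counts was tested on the 35 splits into 4 and 4, and for every count only 1 split, the real one, was as large. The real split gave 5865 changed genes, 1805 changed at least 2-fold, 8959 probe sets and 5728 genes by usage, and the highest of the others gave 0, 0, 225 and 221. Each other split mixes control and amiloride arrays, so the difference between the groups widens its spread and lowers its calls. The low counts of the other splits were thus fixed in part beforehand and give no error rate. At an unadjusted p under 0.05 the highest other split gave 1472 genes and the real one 6740. For the gene lists the real split gave 11 and the highest other 8, with a median of 4 over the other splits. In the 18 splits with 2 control arrays on each side the median was 4 and the highest 8 as well, so camera with its preset correlation called lists between groups balanced for treatment, and a single list call is weak evidence.

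The first pattern weighed is that rises outnumber falls, with 2.92 rises per fall at 2-fold and 8.46 at 4-fold. A floor that hides falls is argued against as the whole cause by 2.06 rises per fall among genes not dim in control (864 against 419, and 1.89 to 2.13 with any array left out), and control replicate 1 by 2.82 rises per fall without it. A part from the floor stays open, since 480 of the 1344 rises but 42 of the 461 falls were dim in control, as were 55.7% of the 4-fold rises. The 3.10 rises per fall above the median of mean signal decide nothing, because that mean lets genes in through their rise. The signal filter does not make the excess either: without it 1356 genes rose and 462 fell at least 2-fold. The zero set by normalization stays open for the excess at 2-fold. Rises per fall dropped to 1.16 after centring on the median of tested genes, as the criterion asked. That centring moved the median difference of the tested genes from -0.14 to -0.33, which by itself lowers rises per fall, so the drop cannot decide. Centring on their median difference, which left a median of -0.05, raised rises per fall to 4.30. At 4-fold 4.73 rises per fall remained after the first centring, which argues against the zero as the whole cause there. A change in RNA levels caused by amiloride stays open and was not tested apart from these.

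The second pattern is that 480 genes dim in the control arrays, under a log2 value of 5.63, rose at least 2-fold. They made up 35.7% of the 2-fold rises, and 33.3% of all tested genes were dim in control. Dim genes were thus hardly more common among these rises than among tested genes. The signal filter used the mean over control and amiloride arrays, so a dim gene could enter the test through its amiloride values. A signal that lifts all dim genes alike is argued against by their median difference of -0.19, which was -0.11 after centring on the median difference of tested genes. The medians of the dim genes in each array differed by -0.16 between the groups, with a standard error of 0.05. Transcription running on from the gene upstream stays open: 254 of 477 risen dim genes had an expressed upstream neighbour on the same strand against 1529 of 3060 dim genes that did not rise, a difference of 3.28 percentage points (two-sided Fisher's exact p = 0.184), while the share with an expressed downstream neighbour differed by -7.13 points (p = 0.00423). The probe set with the smallest change lay at the 5' end 2.11 times as often as at the 3' end (118 against 56 genes, two-sided exact binomial p = 2.99e-06), as transcripts that skip the first exon could give, and the criterion written before was met. In genes bright in control that rose it lay there 4.56 times as often (287 against 63 genes, two-sided Fisher's exact p = 0.000375 against the dim genes), so the lag of the 5' end cannot be told apart from one that risen genes share.

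The third pattern is the 8959 probe sets called as used differently. A signal floor or ceiling that holds back single probe sets of changed genes stays open as a source. Of the called probe sets, 9.67% moved less than, and with, a gene changed by at least 0.5 on the log2 scale. Counting either direction, 29.3% moved less than such a gene. Moves with the gene and further made up 31.2%, and 33.4% lay in genes changed by less. The 9.67% cannot decide. It leaves out held-back probe sets that drifted against the gene, and those called as moving further because others were held back. In genes changed at least 2-fold 15.9% of probe sets were called, against 4.35% in other genes, which this explanation could also give. Calls made by the pooled spread of diffSplice stay open for part of the pattern, as does a change of splicing, which was not tested apart from a change of transcript start or end. The count was 7256 by the splicing index.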

How the results depend on the processing

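Both centrings on the tested genes were chosen after the data were seen. Over all alternatives no named gene or probe set changed direction past the threshold: of 1487 comparisons over 79 genes, 1479 kept their side of the threshold, 7 gained a call (MAPK3 under 5 alternatives, ABL1 and SFRS2 with means over probe sets) and 1 lost it (CD5), and of 405 comparisons over 29 probe sets 403 kept it and 2 lost it by the splicing index, those of SF1 (adjusted p = 0.0562) and HIPK3 (adjusted p = 0.195). The number of genes changed and the number changed at least 2-fold stayed within 1.5 times the reported value in every setting, but their parts did not. With centring on the median of tested genes the 2-fold falls went from 461 to 886 and the lower genes from 3095 to 4875. With means over probe sets there were 1048 rises and 292 falls of at least 2-fold, 161 and 10 of at least 4-fold and 26 rises of at least 8-fold. The number of lists ran from 6 to 11 with each array left out, 6 without control replicate 1 and 7 without amiloride replicate 1. It was 4 with genes under the 50th percentile left out, where all 6 higher lists were lost and the lymphoid list had too few members to be tested. The genes compared with also changed there, the median difference of the tested genes going from -0.14 to 0.01. It was 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 21 by fry. The probe sets called were 5477 with the filter at the 50th percentile and 2964 in genes changed by under 0.5 on the log2 scale, where 2824 genes passed the Simes test, in both cases with fewer probe sets tested. Whether replicate numbers paired the arrays stays open. Same-numbered arrays deviated together with r of 0.336, 0.011, 0.405 and -0.125, and 2 of 4 arrays in each group lay closest to their own number. The highest r between arrays of different numbers was 0.292. With the replicate number as a block the counts were 6380 genes, 1807 at 2-fold, 9117 probe sets, 6399 genes by usage and 10 lists, the lymphoid list being lost. Centring on the median difference of the tested genes gave 3040 higher and 2353 lower genes. Signal near the floor limits what can be seen of falls among dim genes.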

Other observations

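The families and the neighbours named here were examined after the data were seen; the test on the number of probe sets was written before.

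Families of genes that share the letters of their symbol were compared, 48 of them with at least 20 tested genes each. Zinc finger (ZNF) genes had the smallest camera p and were the largest family. Of 321 ZNF genes 137 rose, 61 fell and 123 did not pass the test, with a median log2 difference of 0.33 (camera adjusted p = 0.00411; 0.600 with an estimated correlation). RNF genes, many of which encode ubiquitin ligases, rose in 29 of 60 and fell in 10, USP genes, which encode deubiquitinases, rose in 20 of 39 and fell in 5, and RBM genes, which encode RNA-binding proteins, rose in 15 of 28 and fell in 3. COL genes, which encode collagens, fell in 16 of 29 and rose in 2. The camera adjusted p was 0.0132 for each of these 4 families, and with an estimated correlation it was 0.333, 0.668, 0.286 and 0.637. The KIAA, MED and ZBTB families were called as higher too, with adjusted p values of 0.0224, 0.0263 and 0.0446, and of 0.637, 0.286 and 0.623 with an estimated correlation. None of the 8 calls held with an estimated correlation. The medians of the USP, RBM, ZBTB and RNF families, 0.57, 0.55, 0.45 and 0.41, were larger than that of the ZNF genes. Those of the KIAA and MED families, 0.29 and 0.32, were smaller. The family medians of all 8 kept their sign under both centrings on the tested genes.

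Of the 20 lists that camera did not call, heat shock genes had 4 higher and 8 lower of 17 (adjusted p = 0.432), glycolysis and hypoxia genes 4 higher and 12 lower of 32 (0.255), replicative histones 4 higher and 1 lower of 8 (0.217) and p53 targets 6 higher and 5 lower of 22 (0.505). Targets of BCR-ABL1, STAT5 and ERK had 10 higher and 9 lower of 26 (0.562), the BCL2 family and apoptosis genes 7 higher and 4 lower of 28 (0.562) and endoplasmic reticulum chaperones 8 higher and 3 lower of 24 (0.530). Genes of G1, S phase and replication had 4 higher and 15 lower of 42 (0.432), lysosome and V-ATPase genes 7 higher and 2 lower of 32 (0.432), and proteasome genes 5 higher and 2 lower of 27 (0.651). NF-kappa-B genes had 3 higher and 4 lower of 15 (0.651), NRF2 genes 4 higher and 6 lower of 24 (0.651), polyamine genes 2 higher and 2 lower of 16 (0.651) and interferon genes 3 higher and 2 lower of 14 (0.966). Ribosomal proteins had 3 higher and 0 lower of 28 (0.687) and oxidative phosphorylation 2 higher and 2 lower of 32 (0.815). In the NF-kappa-B, endoplasmic reticulum, proteasome, ribosomal protein, oxidative phosphorylation and transporter lists the median and the mean differed in sign, and in the interferon list both were negative while camera pointed up, so the direction of these lists is not settled. Centring on the median of tested genes turned the balance of several lists. It gave 4 higher and 7 lower for lysosome and V-ATPase genes, 2 and 6 for the proteasome and 6 and 9 for the BCL2 family. It gave 6 and 8 for endoplasmic reticulum chaperones, 8 and 9 for targets of BCR-ABL1, and 2 and 5 for both ribosomal proteins and interferon genes. Centring on the median difference left more genes higher than lower in each, so their direction is not settled either.

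Among the 10 largest rises, 7 had an upstream neighbour on the same strand that was above the dim limit in control arrays. Such neighbours are common. Among dim genes, 254 of 477 that rose at least 2-fold had an expressed upstream neighbour. So did 1529 of 3060 dim genes that did not rise (two-sided Fisher's exact p = 0.184). The 7 of 10 were not tested against these shares, so the pairs named here give no evidence of transcription running on from upstream. PDCL2 followed NMU, at 9.06 ± 0.35 in control arrays (SD, n = 4), PDZK1IP1 followed TAL1 at 8.51 ± 0.14, and OVGP1 followed WDR77 at 11.15 ± 0.12, which itself fell by 0.71 on the log2 scale (adjusted p = 0.0022). The upstream neighbours of VDAC2, TMEM171 and AOC3, which are SAMD8, FCHO2 and AOC2, themselves rose by 2.13, 2.08 and 3.32 on the log2 scale. Those of PDCL2 and RRH, which are NMU and GAR1, rose by 0.56 and 0.59, and the neighbours of C1orf162, SGK1, PDZK1IP1 and SLC16A4 were not called. Strands were read from the order of probe set IDs, which gave the known strand for 34 of 34 genes checked.

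A hypothesis written before its test was that genes with few exons fell more often. Genes that fell at least 2-fold had a median of 9 probe sets and the other tested genes 12, a difference of -3 for the explanation that genes with few exons fell more often than genes with many (two-sided permutation test, 100000 draws, p = 1e-05, the smallest the draws can give). Under 10 probe sets were carried by 52.9% of the genes that fell, 32.1% of those that rose at least 2-fold and 37.0% of all tested genes. A larger loss of transcripts with few exons could give this, but it was not tested apart from other causes. A median over few probe sets also varies more, which would add large rises as well as large falls. Genes that rose at least 2-fold had a median of 13 probe sets, which argues against that spread as the whole cause.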
